A study of Mus musculus with 6 samples.

How the data were processed

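Bulk RNA-seq was measured in 6 libraries of tdTomato-positive cells sorted from mouse lungs 4 days after delivery of an adenovirus carrying Cre under the surfactant protein C promoter. The sources differ on the route: the treatment label gives intrathecal injection, and the design text gives delivery through the trachea. Cre switches on the tdTomato reporter, and in mice with floxed Kat7 it also deletes part of that gene. The labels call the sorted cells alveolar type 2 (AT2) cells. They give 3 Kat7-deficient mice and 3 Kat7-proficient mice, each a separate animal.

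The deposited values are whole-number read counts per gene in 1 table, which the authors made with STAR 2.7.0 and featureCounts of Subread 2.0.6 against mm10, per the submitters' processing notes. The notes also list DESeq2 1.4.4, and its role is not given in the sources used here. The annotation release and the strand setting of the counting are not given in the sources used here either. It is therefore not known whether reads of overlapping or antisense genes were told apart. Reads shared by near-identical gene copies may have been split or dropped. The table held 48440 genes. Every row named a gene, so 0 rows were left out, and 48058 of the identifiers (99.21%) matched a gene symbol and a biotype in GENCODE release M21. Among those symbols, 62 were repeats of another row's symbol.

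Columns were assigned by name alone. Those named K1, K2 and K3 were taken as the Kat7-deficient group. THC1 matched a label, and THC4 and THC5 were taken as Kat7-proficient from the THC prefix, because the labels number those mice differently. No individual mouse was assigned to the columns other than THC1. All 6 count columns were used.

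Total counts ran from 7097333 in THC5 to 27895269 in THC1. The main test was edgeR 4.0.16 in R 4.3.3, with TMM normalization, filterByExpr by group (minimum count 10, minimum total 15), robust glmQLFit and glmQLFTest, a group term only, and Benjamini-Hochberg adjustment over the 19915 genes tested. The threshold was an adjusted p of 0.05. Fold changes are deficient minus proficient on the log2 scale. The SE beside an edgeR fold change is its absolute value divided by the square root of the quasi-likelihood F statistic, not a standard error given by the fit. CPM values use TMM-scaled library sizes, and log2 CPM values add a prior count of 2. With 3 libraries against 3 the fit had 4 residual degrees of freedom. The common biological coefficient of variation was 1.12.

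Before the data were examined, 36 gene lists were written, covering alveolar identity, other lung cell types, chromatin, immune, metabolic, stress, proliferation, signalling and RNA composition genes. Camera (limma 3.58.1) was run on log2 CPM with a preset inter-gene correlation of 0.01, over the 35 lists with at least 3 measured members, with adjustment over the lists. It was repeated with an estimated correlation and with fry. Member counts were adjusted over all genes and, separately, over the list alone. The naming rule, also set beforehand, took Kat7, up to 10 genes of largest change and 5 of smallest p per direction among genes past the threshold, with a mean log2 CPM of at least 2 and groups that did not overlap, and up to 4 members of smallest p per described list, passing or not. As no gene passed, the named genes are Kat7 and list members. Which lists to describe, and how many members of each to name, was chosen after their values were seen. Some genes stand in more than 1 list: Etv5 in the AT2 and ERK lists, Nkx2-1 and Cebpa in the AT2 and transcription factor lists, and Cdkn1a in the transitional and p53 lists. Ccn2 stands in the transitional and YAP lists, Itgb6 in the transitional and TGF-beta lists, Nupr1 in the transitional and integrated stress lists, Sesn2 in the p53 and integrated stress lists, Atf3 in the integrated stress and immediate early lists, and Btg2 in the p53 and immediate early lists.

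The gene test was tested on simulated counts drawn from the real means, library sizes and dispersions of the 19915 genes for this comparison, in 5 runs with 200 changed genes each. It recovered 5 of 500 genes changed by 2 on the log2 scale (1%) and 102 of 500 changed by 4 (20.4%). Of 109 calls in all, 2 were false. Changes of this size are therefore mostly missed in these libraries, and a gene that does not pass is not shown to be the same in both groups.

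For the gene counts, 13 other settings fixed beforehand were run, besides leaving out each of the 6 libraries in turn. They included DESeq2 1.42.0, limma-voom, other scalings, other filters, other thresholds and other gene subsets. After the data were examined, 7 more were added, with their thresholds set from the library values. These were terms for sex, for macrophage marker level, for library class and for the protein-coding share, a fit without THC1 and THC4, a fit without K1, K2 and THC5, and a fit without rRNA, satellite-like and mitochondrial genes. Library class separated K1, K2 and THC5, with under 96% of counts on protein-coding genes, from the other libraries. Fits that left 1 library in a group assume that it varies like the libraries of the other group. A planned fit with mouse number as a block was not run. Tables were handled with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots with matplotlib 3.10.9.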

Results

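Gene expression was measured in tdTomato-positive lung cells from 3 Kat7-deficient mice (libraries K1, K2 and K3) and 3 Kat7-proficient mice (THC1, THC4 and THC5). KAT7 is a histone acetyltransferase of the MYST family. The comparison asks which transcripts differ in these cells 4 days after Cre delivery. Total counts were 11189713 in K1, 14672514 in K2, 26299943 in K3, 27895269 in THC1, 22298098 in THC4 and 7097333 in THC5.

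Kat7 (ENSMUSG00000038909.16, chromosome 11, 95274259 to 95310246 in mm10, protein-coding) was measured first, as a check of the genotype labels. Its level was 67.7 CPM in K1, 28 CPM in K2 and 108.2 CPM in K3, against 130.7 CPM in THC1, 93.2 CPM in THC4 and 75.6 CPM in THC5. The means were 68 ± 40.1 CPM and 99.8 ± 28.1 CPM (SD, n = 3 each). The log2 fold change was -0.55 (SE 0.55), with an adjusted p of 0.9999 by edgeR's quasi-likelihood test. An exact two-sided permutation test of the log2 CPM values gave p = 0.4, where 0.1 is the smallest p that 3 libraries against 3 allow. K3 lay above 2 of the 3 control libraries. Counts over the whole gene include exons that may lie outside the floxed part, so this level neither shows nor excludes the deletion, and the groups are called the libraries labelled Kat7-deficient and Kat7-proficient below. The log2 fold change was -1.25 without K3, -0.24 without K2 and -0.29 without THC1.

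The libraries labelled Kat7-deficient had higher levels of AT2 and alveolar type 1 (AT1) marker genes, and lower levels of macrophage markers and interferon-stimulated genes. The median log2 fold change was 2.14 over 20 AT2 markers and 0.91 over 20 AT1 markers. It was -2.41 over 14 macrophage and monocyte markers and -1.48 over 23 interferon-stimulated genes. The control THC5 lay within the deficient range in mean macrophage marker level (4.91 against 4.53 to 5.24 log2 CPM), and without THC1 and THC4 that median turned to 0.49. The direction of the camera test stayed lower in that fit. In mean interferon-stimulated gene level K3 (7.11) lay above THC5 (6.85). These differences were called for the lists by camera with its preset correlation, and for none of them with an estimated correlation (lowest adjusted p = 0.364 with an estimated correlation) or by fry (lowest adjusted p 0.0979).

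Gene by gene, edgeR called 0 of 19915 genes at an adjusted p under 0.05, and 758 genes (3.81%) had an unadjusted p under 0.05. That edgeR share lies below the fraction of 0.05 that evenly spread p values would give. DESeq2 called 118 genes, of which 41 rose and 77 fell in its test, with 1330 at an unadjusted p under 0.05. Limma-voom called 0 genes, with 1566 at an unadjusted p under 0.05. EdgeR without a low-count filter called 36 genes, 33 of them shared with DESeq2, and without THC5 it called 4. The groups did not overlap for 2302 genes (11.6%), where chance gives 10%.

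The libraries differed in composition in ways that crossed the genotype groups. The share of counts on protein-coding genes was 94.41% in K1, 94.14% in K2 and 87.4% in THC5, against 97.87% in K3, 98.41% in THC1 and 98.45% in THC4. Ribosomal RNA genes took 1.41%, 1.87% and 3.86% of counts in K1, K2 and THC5, and at most 0.148% in the other libraries. Gm10800, a satellite-like transcript, took 5.43% of counts in THC5. Counts on the Y-linked genes Ddx3y, Kdm5d, Uty and Eif2s3y came to 5316 in THC1 and 4830 in THC4 and to 0 in the other 4 libraries, while Xist had 0 counts in THC1 and THC4 and at least 537 elsewhere. Sex therefore differed within the control group, and both male libraries were controls. The median correlation of log2 CPM across genes was 0.858 within the libraries labelled Kat7-deficient, 0.584 within the controls and 0.725 between the groups. The highest correlation of any pair crossed the groups, at 0.908 between K3 and the control THC4. K3 correlated at 0.858 with K2 and 0.803 with K1. The first principal component held 54.3% of the variance and did not separate the groups.

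**Figure D1:**
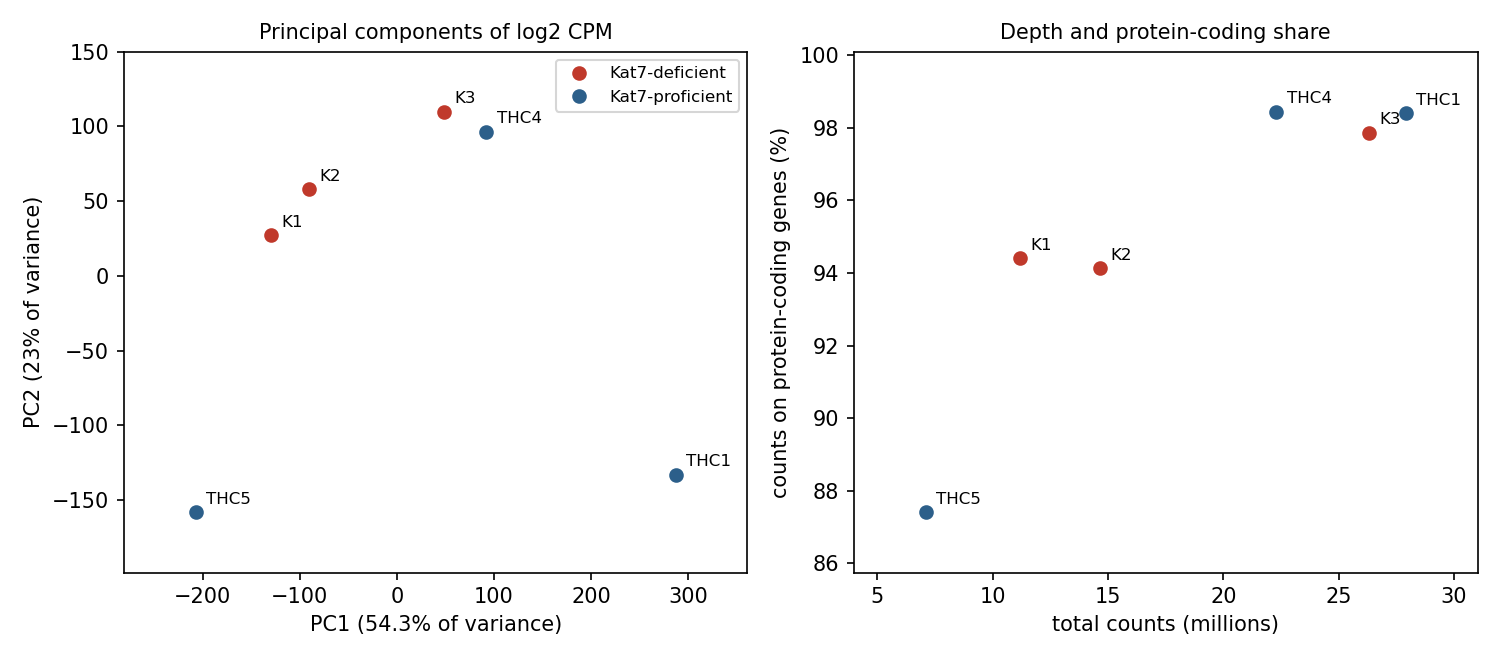
Left, the first and second principal components of log2 CPM for each library; right, total counts against the percentage of counts on protein-coding genes, with libraries labelled Kat7-deficient in red and Kat7-proficient in blue. K1, K2 and THC5 hold 94.41%, 94.14% and 87.4% of counts on protein-coding genes, below K3, THC1 and THC4.

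AT2 markers, which include the surfactant genes, were higher in the libraries labelled Kat7-deficient for 19 of 20 members. Sftpd, a surfactant collectin, was at 1679 ± 442 CPM against 370 ± 104 CPM (SD, n = 3 each; log2 fold change 2.18, SE 0.46). Sftpb, a surfactant protein needed for the alveolar film, was at 1231 ± 417 CPM against 289 ± 96.7 CPM (2.09, SE 0.48). The transcription factor gene Etv5 and the mucin gene Muc1 had log2 fold changes of 1.53 (SE 0.38) and 2.80 (SE 0.69). Adjusted over the list alone, 14 of the 20 markers rose, these 4 among them (adjusted p 0.0178 each by edgeR), and 0 rose adjusted over all genes. Mean marker level was 8.07, 8.97 and 8.62 log2 CPM in K1, K2 and K3, against 5.45 in THC1, 7.18 in THC4 and 6.18 in THC5. The list had an adjusted p of 1.02e-17 by camera, and adjusted p = 0.364 with an estimated correlation. In the same libraries macrophage marker level was 9.06 in THC1 and 8.87 in THC4, against 4.91 in THC5 and 4.84, 4.53 and 5.24 in K1, K2 and K3. Without THC1 and THC4, an alternative added after seeing the data, the AT2 median was 1.99 against the single control THC5.

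AT1 markers had positive fold changes for 20 of 20 members, and 0 passed adjusted over the list alone or over all genes. Vegfa, which encodes an endothelial growth factor, was at 184 ± 15.5 CPM against 53.9 ± 28.3 CPM (log2 fold change 1.77, SE 0.47). The water channel gene Aqp5 and Gprc5a had log2 fold changes of 2.56 (SE 0.81) and 2.22 (SE 0.76). Without THC4, Aqp5 was at 3.88 and the median of the list at 1.97. The list had an adjusted p of 2.17e-06 by camera, and adjusted p = 0.427 with an estimated correlation. AT1 level was 2.2 log2 CPM in THC1, 5.35 in THC4 and 3.86 in THC5, against 5.88, 6.06 and 5.28 in K1, K2 and K3, so THC4 lay above K3. Fibroblast marker level was likewise lowest in THC1 (5.1 log2 CPM) and THC5 (6.8), with THC4 at 8.68, K3 at 8.29 and K1 and K2 at 8.79 and 8.73. Without K1, K2 and THC5, which left K3 as the only deficient library, the median was 0.61 and camera made no call (adjusted p 0.475; over the 17 alternatives the adjusted p ran from 5.62e-10 to 0.475).

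Macrophage and monocyte markers had negative fold changes for 14 of 14 members. Chil3, a chitinase-like protein of alveolar macrophages, was at 63.6 ± 78.4 CPM against 7562 ± 7106 CPM (log2 fold change -6.90, SE 1.84), and its reads may be shared with near-identical Chil4. The mannose receptor gene Mrc1 was at 12.8 ± 10.1 CPM against 313 ± 268 CPM (-4.62, SE 1.31). Ly6c2, whose reads may be shared with near-identical family members, and the Fc receptor gene Fcgr3 had log2 fold changes of -2.68 (SE 0.71) and -2.62 (SE 0.72). Adjusted over the list alone 5 members fell, and 0 fell adjusted over all genes. The list had an adjusted p of 1.7e-14 by camera, and adjusted p = 0.364 with an estimated correlation. For 10 of the 14 markers THC1 and THC4, the libraries with Y-linked counts, both lay above the other 4 libraries: Chil3 was at 8312 CPM in THC1, 14263 CPM in THC4 and 110 CPM in THC5. For 5 of the 14 THC5 also lay above each library labelled Kat7-deficient: C1qa, C1qb and Ccr2, named here after their values were seen, and Fcgr3 and Ly6c2. C1qa and C1qb were at 900 and 1117 CPM in THC5, above THC1 and THC4 too. Ccr2 was nearly level, at 101.8 CPM in THC5 and 101.1 CPM in K3. Ly6c2 was at 292 CPM in THC5 and 213 CPM in THC4, against at most 111 CPM in K1, K2 and K3, and Fcgr3 was at 173 CPM in THC5 against at most 149 CPM. Without THC1 and THC4 the only control left was THC5, whose level (4.91) was close to the deficient mean (4.87). The median was then 0.49, with Ly6c2 at -2.07 and Fcgr3 at -0.55, while the direction of the camera test stayed lower. Over the 17 alternatives the adjusted p of the list ran from 5.36e-19 to 0.884.

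Interferon-stimulated genes had negative fold changes for 21 of 23 members. Isg15, a ubiquitin-like antiviral protein, was at 118 ± 56.1 CPM against 538 ± 101 CPM (log2 fold change -2.20, SE 0.48), with THC5 at 590 CPM. Ifit3, an antiviral effector whose reads may be shared with a near-identical copy, was at 58.9 ± 41.9 CPM against 501 ± 321 CPM (-3.09, SE 0.82). Xaf1 and Rsad2 had log2 fold changes of -1.74 (SE 0.44) and -2.47 (SE 0.66). Adjusted over the list alone 10 members fell, and 0 fell adjusted over all genes. The list had an adjusted p of 7.96e-22 by camera, and adjusted p = 0.364 with an estimated correlation. Mean level was 5.66, 5.76 and 7.11 log2 CPM in K1, K2 and K3, against 8.19 in THC1, 8.1 in THC4 and 6.85 in THC5, so K3 lay above THC5. THC1 and THC4 were also the libraries with high macrophage markers (9.06 and 8.87 log2 CPM). Without them THC5 was the only control left, and the median was -0.79 with no call by camera (adjusted p 0.091; over the 17 alternatives from 3.21e-24 to 0.364).

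**Figure D2:**
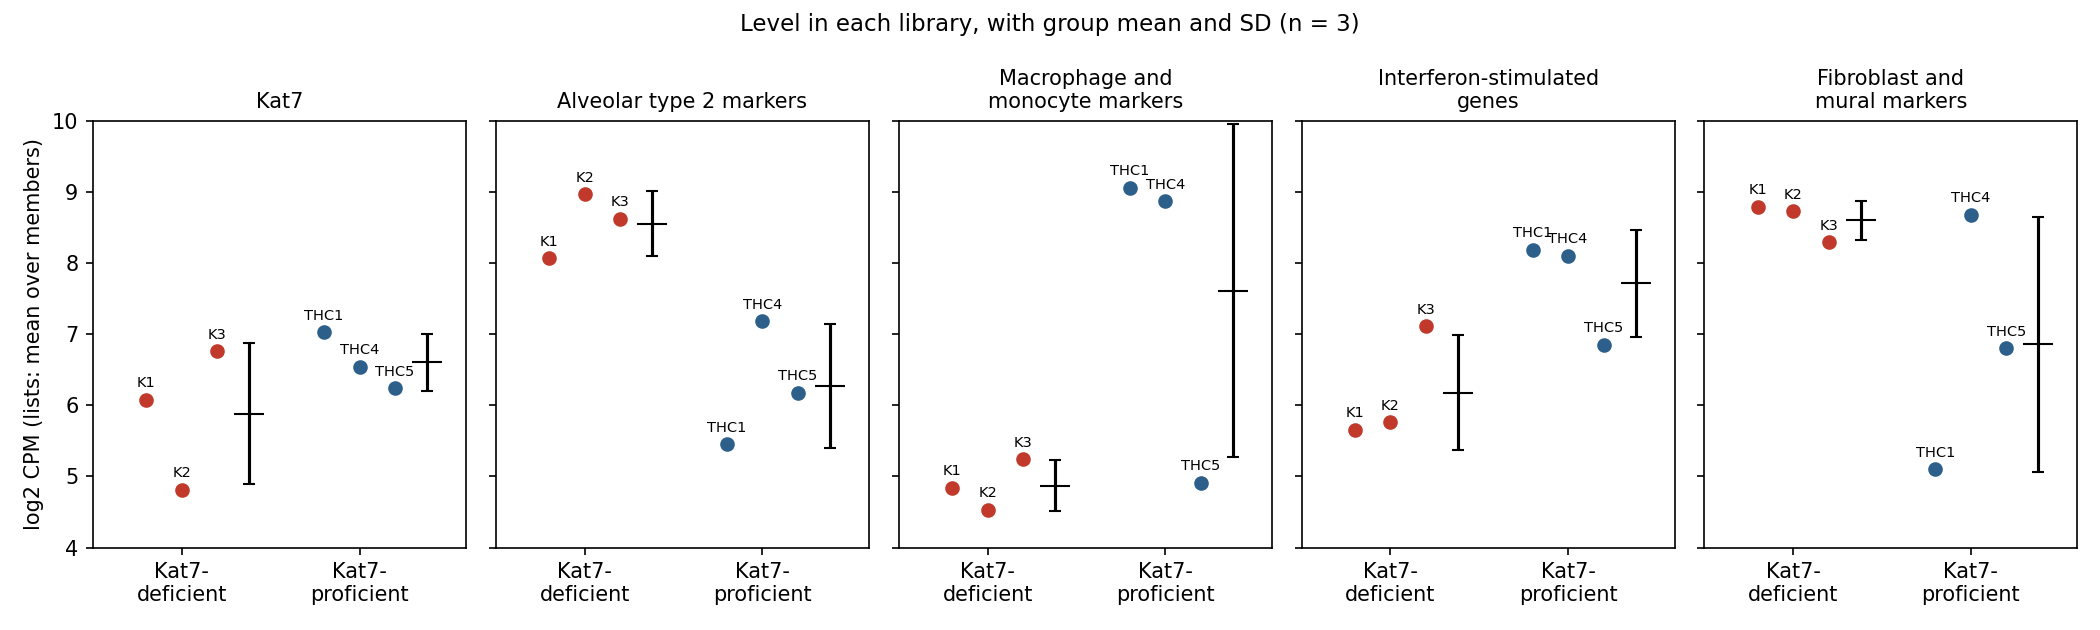
Level of Kat7 and mean level of 4 gene lists in each library, in log2 CPM, with libraries labelled Kat7-deficient in red, Kat7-proficient in blue, and black bars for the group mean and SD (n = 3). AT2 markers lie at 8.07 to 8.97 in K1, K2 and K3 and at 5.45 to 7.18 in the controls, and macrophage markers are high in THC1 (9.06) and THC4 (8.87) but not in THC5 (4.91).

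Fibroblast and mural markers were positive for 10 of 12 members (median 0.89; adjusted p 0.000918 by camera, and adjusted p = 0.567 with an estimated correlation). Col3a1 and Col1a1, fibrillar collagen genes, had log2 fold changes of 2.59 (SE 0.69) and 2.41 (SE 0.77). Col3a1 stood at 8484 ± 2903 CPM in the libraries labelled Kat7-deficient, where the surfactant gene Sftpc, named here after its values were seen, stood at 23408 ± 6538 CPM. Fatty acid synthesis genes were positive for 14 of 16 members (median 0.64; adjusted p 0.000378, and adjusted p = 0.427 with an estimated correlation), with the desaturase gene Scd1 at 2.74 (SE 0.77) and the synthase gene Fasn at 1.47 (SE 0.46). No member of either list passed adjusted over the list alone or over all genes. Without THC5, the library with the lowest depth and protein-coding share, camera called neither list (adjusted p 0.155 and 0.209). The fibroblast median was 0.58 without K1 and 2.30 without THC4. Fibroblast marker level was 5.1 log2 CPM in THC1 and 6.8 in THC5, against 8.68 in THC4 and 8.29 to 8.79 in K1, K2 and K3. Over the 17 alternatives, the adjusted p ran from 1.99e-08 to 0.928 for the fibroblast list and from 1.9e-06 to 0.427 for the fatty acid list.

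Genes of the mitochondrial and translational machinery also moved as lists. Nuclear oxidative phosphorylation genes were negative for 70 of 76 members (median -0.36; adjusted p 6.92e-09 by camera, and adjusted p = 0.427 with an estimated correlation). Ribosomal protein genes were negative for 75 of 77 (median -0.49; adjusted p 2.8e-06, and adjusted p = 0.664 with an estimated correlation). Without THC5 the ribosomal median was 0.20 and the direction of the test turned (adjusted p 0.728). Mean ribosomal protein gene level was 8.08 log2 CPM in THC5 and 6.68 to 7.12 in the other libraries, and THC5 also had the lowest protein-coding share. Mitochondrially encoded genes were positive for 12 of 12 (median 1.48; adjusted p 0.00143, and adjusted p = 0.567 with an estimated correlation). Among them mt-Cytb was at 1795 CPM in K1 and 2559 CPM in K2 but 376 CPM in K3, within 327 to 406 CPM in the controls. K1 and K2 also had a lower protein-coding share than K3. The share of all counts on the mitochondrial chromosome was 1.01% in K1, 1.22% in K2 and 0.98% in THC5. It was 0.173% in K3, 0.191% in THC1 and 0.202% in THC4, so it went with library class across the groups. THC5 had the lowest protein-coding share but mt-Cytb at 368 CPM. Its mean mitochondrial list level was 5.39 log2 CPM, against 6.45 and 6.99 in K1 and K2 and 4.48 to 4.92 in K3, THC1 and THC4. Without K2 the mitochondrial median was 0.91 and camera did not call the list (adjusted p 0.0523). Nor did camera call it with sex or macrophage marker level as a term, both added after seeing the data (adjusted p 0.458 and 0.772). Without K1, K2 and THC5, which left K3 as the only deficient library, the direction of the test turned. Over the 17 alternatives the adjusted p of the mitochondrial list ran from 6.4e-09 to 0.772. No member of these 3 lists passed adjusted over the list alone or over all genes.

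Of the 35 lists tested, camera with the preset correlation called 15, with 10 higher and 5 lower in the libraries labelled Kat7-deficient. The calls not yet described were the transitional alveolar state (median 0.51; adjusted p 0.0392), WNT targets (0.87; 0.0469), ERK pathway targets (0.57; 0.0392), YAP and TEAD targets (1; 0.0313), alveolar and foregut transcription factors (0.32; 0.0313) and MHC class I presentation (-0.24; 0.0255). With an estimated correlation the adjusted p values of these 6 lists were 0.567, 0.567, 0.427, 0.567, 0.427 and 0.567. In the transitional list 1 gene rose adjusted over the list alone, the stress-responsive gene Ndrg1 (log2 fold change 1.97, SE 0.43), while the galectin gene Lgals3 was at -1.81 (SE 0.52). In the ERK list 1 gene rose adjusted over the list alone, Etv5, which is also an AT2 marker. Adjusted over all genes, 0 members of these lists passed. Each of the 6 lists lost its camera call without at least 1 library. The transitional list lost it without K3 (adjusted p 0.11), THC1 (0.126) and THC5 (0.579), and its median was 1.16 without THC4. WNT targets lost it without K3 (0.126), THC1 (0.175) and THC5 (0.0509), with medians of 0.51, 1.83 and 1.70 without THC1, THC4 and THC5. ERK targets lost it without K2 (0.118), K3 (0.096), THC4 (0.0773) and THC5 (0.406). YAP and TEAD targets lost it without K1 (0.0611), K3 (0.096), THC1 (0.0504) and THC5 (0.582), with medians of 0.54 without THC1 and 1.74 without THC4. The transcription factor list lost it without K2 (0.0523) and THC5 (0.155), with medians of 0.12, 0.49 and 1.10 without K1, THC1 and THC5. MHC class I genes lost it without K1 (0.238), THC1 (0.182) and THC4 (0.092), with medians of -0.07, -0.81, -0.14 and -0.39 without K1, K3, THC4 and THC5.

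**Figure D3:**
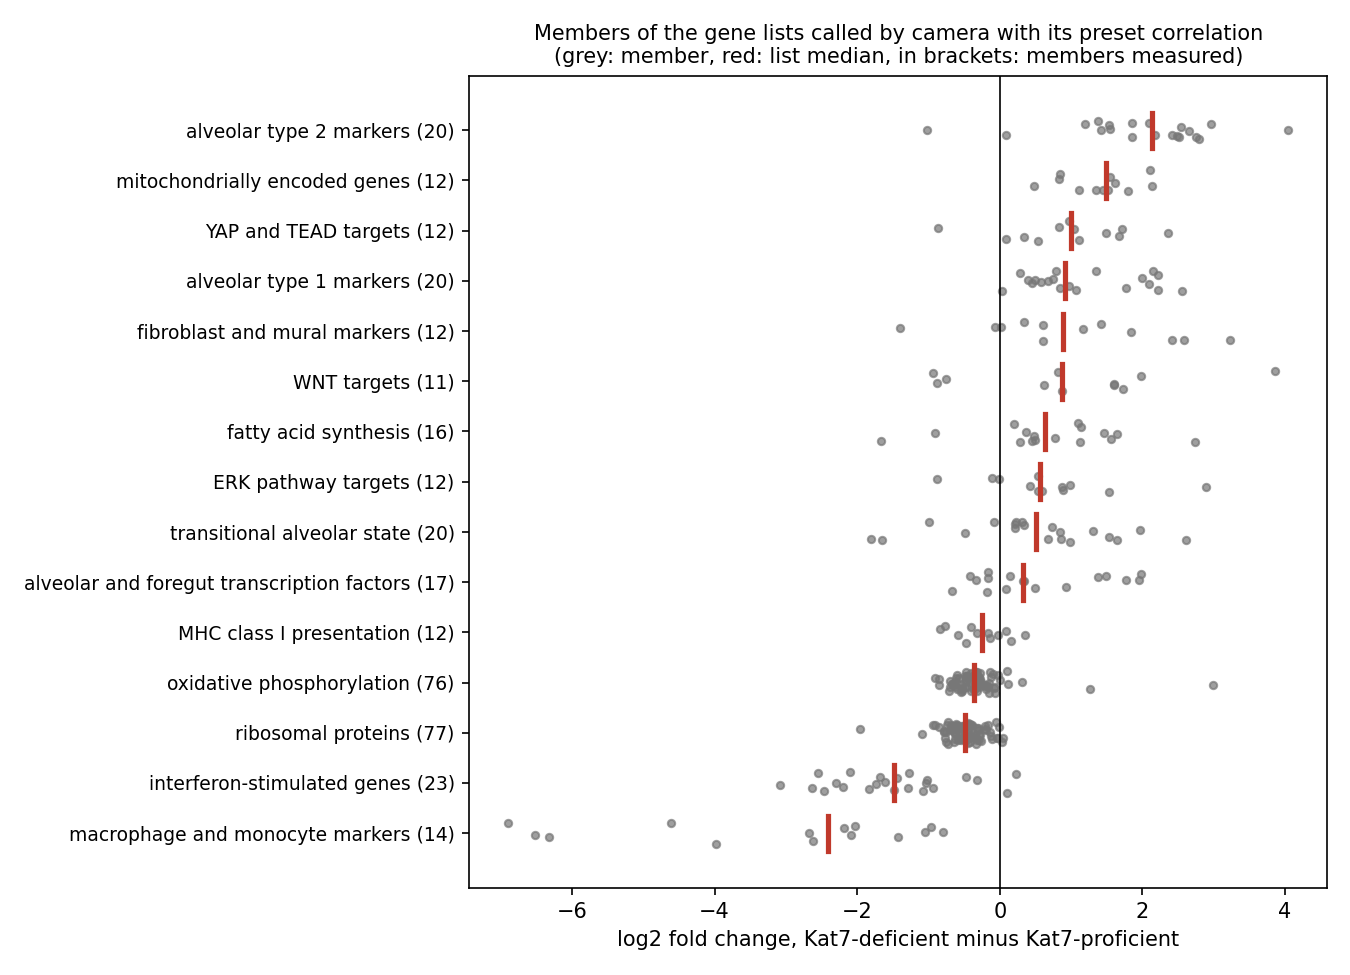
Log2 fold change (deficient minus proficient) of each measured member, in grey, and the median, in red, for the 15 gene lists called by camera with its preset correlation. Medians run from -2.41 for macrophage and monocyte markers to 2.14 for alveolar type 2 markers, and none of the 15 calls held with an estimated correlation.

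Camera did not call the remaining 20 lists in all 6 libraries, with adjusted p values from 0.0527 to 0.986. Among markers of other cell types, median log2 fold changes were 0.41 for club cells, 0.75 for ciliated cells, -1.30 for basal and neuroendocrine cells, -0.16 for other leukocytes, -0.26 for endothelium and -1.65 for erythroid cells. The difference in mean level had the other sign for other leukocytes (0.40 log2 CPM) and erythroid markers (0.27), and fry also gave the erythroid list as higher. The neutrophil genes S100a9 and S100a8 were at -3.56 (SE 0.91) and -2.40 (SE 0.66). The median was 0.31 for subunits of KAT7 complexes and -0.01 for other lysine acetyltransferases. It was 0.64 for MHC class II presentation, 0.52 for inflammatory cytokines and NF-kB targets and 0.47 for TGF-beta targets. Metabolic lists gave -0.36 for glycolysis and hypoxia and 0.09 for cholesterol synthesis, whose mean of -0.04 had the other sign. Stress lists gave -0.35 for p53 targets, -0.13 for the integrated stress response (0.01 as the difference in mean level, and higher by fry), 0.47 for the unfolded protein response and 0.18 for the immediate early and dissociation response. In the last of these the heat shock genes Hspa1b and Hspa1a, near-identical copies, were at 1.68 (SE 0.48) and 1.68 (SE 0.52). Medians were 0.11 for the mitotic cell cycle, -0.10 for DNA replication and licensing and 0.26 for gastric and mucinous lineage genes, whose mean of -0.04 had the other sign. Among the sex-linked genes 1 of 5, Xist, passed the count filter, so that list was not tested.

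With 1 library left out, camera at the preset correlation called 15 of these 20 lists in at least 1 of the 6 fits. With an estimated correlation, run in all 6 libraries only, none of the 20 was called (adjusted p = 0.427 to 0.99 with an estimated correlation). Without K3, lower calls were DNA replication (adjusted p 1.16e-05), glycolysis and hypoxia (0.00173), other leukocytes (0.00311), endothelium (0.00979), p53 targets (0.0146) and cholesterol synthesis (0.0226). Without THC5, p53 targets (0.000103), endothelium (0.00206) and glycolysis and hypoxia (0.00245) were called lower, and MHC class II (0.0109) and the mitotic cell cycle (0.0301) higher. Without THC1, erythroid markers (0.00065) and DNA replication (0.0188) were called lower, and club cell markers (0.00266) and the immediate early response (0.0246) higher. Without THC4, TGF-beta targets (0.0117), inflammatory cytokines (0.0195), the unfolded protein response (0.0195) and the immediate early response (0.0413) were called higher. Without K2, the mitotic cell cycle (0.00224), MHC class II (0.0428) and the unfolded protein response (0.0428) were called higher, and other lysine acetyltransferases (0.0428) lower. Without K1, MHC class II (0.0175) and the mitotic cell cycle (0.028) were called higher. The direction turned for 12 of the 20 lists in at least 1 of these fits, none of them called there (adjusted p 0.0847 to 0.973). Erythroid, gastric and unfolded protein response genes turned without K3 and without THC5, and MHC class II and mitotic genes without K3. Gastric and cholesterol genes turned without K1 and without K2, cholesterol and endothelial genes without THC4, and ciliated and p53 genes without THC1. Club, inflammatory and immediate early genes turned without THC5. Alternatives added after seeing the data also called some of the 20 lists in the unturned direction, among them the immediate early response with sex as a term (adjusted p 1.2e-07 by camera). In the added alternatives, 3 lists were called in the turned direction, higher in the libraries labelled Kat7-deficient. These were p53 targets with sex as a term (adjusted p 0.0254), with macrophage level as a term (0.0155) and without THC1 and THC4 (0.0124), endothelial markers without THC1 and THC4 (0.0389), and DNA replication without K1, K2 and THC5 (0.0396).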

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

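Terms for sex, macrophage marker level, library class and protein-coding share, and the fits without THC1 and THC4, without K1, K2 and THC5 or without rRNA, satellite-like and mitochondrial genes, were chosen after seeing the data. The edgeR count of 0 genes changed became 118 with DESeq2 (41 higher, 77 lower) and 36 without a low-count filter (9 higher, 27 lower). The cause was not tested. It ran from 0 to 4 with each library left out, the 4 lower genes being those without THC5, and was 0 in the other alternatives run. Kat7 kept its negative fold change in 23 of 24 alternatives, passed in none (adjusted p 0.592 to 1), ran from -1.25 to -0.24 with each library left out, and was 0.05 without THC1 and THC4, where 1 control remained. Of the 26 named list genes, 18 passed with DESeq2 and 6 without a low-count filter. Mrc1 changed sign to 0.30 with sex as a term, 0.33 with macrophage marker level as a term and 0.43 without THC1 and THC4. These settings remove the libraries or the trend in which its level is high. The count of 15 called lists became 0 with an estimated correlation, 0 by fry and 9 without K1, K2 and THC5, where K3 alone stood against THC1 and THC4. Those 9 held only 4 of the 15 (AT2, macrophage, interferon and oxidative phosphorylation). The count ran from 13 to 18 with each library left out, of which 7 to 13 were among the 15 in the same direction, and 5 lists (AT2, AT1, macrophage, interferon and oxidative phosphorylation) kept their calls in all 6 such runs. The median of all genes shifted by 0.212 with limma-voom, -0.174 with sex, -0.189 with macrophage marker level and 0.17 with the protein-coding share as a term, and -0.195 without THC1. No paired analysis was possible because the column names of the groups share only the number 1, and no source pairs the mice, so the fit with mouse number as a block was not run. Depth limits THC5 most, at 7097333 counts. THC1 had the most counts but the fewest genes with a count, 17500 against 23561 to 31217 in the other libraries. Its column name also carries sample number 19, against 4 to 8 for the others. What these differences did to the fold changes was not tested apart from leaving THC1 out.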

Other observations

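The tests with terms for sex, macrophage level and library class, and those on THC5 and on fibroblast against macrophage markers, were chosen after the result was seen. The tests on a second macrophage set and on pan-epithelial genes were written before the values of those genes were seen, although the patterns, the high macrophage level of THC1 and THC4 and the AT2 median were known by then. Without THC5, edgeR called 4 genes, Pparg, Ms4a8a, Ear2 and Ear1, named after their values were seen. Each was lower in the libraries labelled Kat7-deficient (log2 fold changes -5.12, -5.95, -7.02 and -9.22, adjusted p 0.0229 each). In THC5, the library of lowest depth, their counts were 42, 40, 0 and 0. Counts in K1, K2 and K3 were 65, 75 and 78 for Pparg and 30, 45 and 58 for Ms4a8a. They were 44, 62 and 92 for Ear2 and 6, 4 and 4 for Ear1. In CPM, THC5 lay above each library labelled Kat7-deficient for Pparg and Ms4a8a. Pparg is a regulator of alveolar macrophage identity. Ear1 and Ear2 are close copies whose reads may be shared. Of the 77 genes lower by DESeq2, 59 had a higher count share in both THC1 and THC4 than in each of the other 4 libraries. Selection as lower in K1, K2 and K3 largely fixes that part of the comparison, and only the part against THC5 is free. For 30 of the 77 the share in both was over 4 times that in THC5. DESeq2 calls also included 6 AT2 markers that rose, and 4 macrophage and 4 interferon markers that fell.

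All 10 splits of the 6 libraries into 3 and 3 gave 0 genes at an adjusted p under 0.05 by edgeR, so 10 of 10 gave as many as the real split. With 0 genes in the real split no other outcome was possible, and this count tests nothing. The real split had 758 genes at an unadjusted p under 0.05 and the highest other split 4170. That other split set K1, K2 and THC5 against K3, THC1 and THC4, which follows depth and protein-coding share and points to a structure of the samples.

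Mean macrophage marker level was low in the libraries labelled Kat7-deficient and in THC5 (4.91 log2 CPM), although 5 of 14 members, among them Ly6c2 and Fcgr3, were higher in THC5 than in each library labelled Kat7-deficient. Over a second set of 12 alveolar macrophage genes, the median gap between the lower of THC1 and THC4 and the highest other library was 1.56 log2 CPM, above 0 for 9 genes and below it for Itgax, Mpeg1 and Vat1, with Lpl at 11.03 and 10.51 against at most 8.15. None of these genes, 0 of the 12, stands in another of the lists. A candidate explanation is macrophage RNA in THC1 and THC4. A clean tdTomato-positive sort would remove unlabelled macrophages. The sort cannot be taken as clean in every library, since the fibroblast marker Col3a1 stood at 8484 CPM in the libraries labelled Kat7-deficient. In the controls it stood at 526 CPM in THC1, 2533 CPM in THC4 and 1177 CPM in THC5. Fibroblast RNA does not show whether macrophages passed the sort in THC1 and THC4. A genotype effect stays open, because THC5, which lay 0.04 log2 CPM above the deficient mean over the list, is 1 library. Against it alone the members differed, with Ly6c2 still at -2.07, Fcgr3 at -0.55 and Mrc1 at 0.43. Sex cannot be told apart from macrophage content, since the 2 male libraries are the same ones and the list median became 0.35 with sex as a term. The direction of the camera test stayed lower with that term.

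Interferon-stimulated genes were lower in the libraries labelled Kat7-deficient, by camera at its preset correlation only (adjusted p = 0.364 with an estimated correlation, 0.299 by fry). Library class as the whole cause is argued against by a median of -1.32 with class as a term, from -1.48 in all libraries (adjusted p 1.23e-15 by camera at the preset correlation). That fit rests on THC5 alone against K1 and K2, and on K3 alone against THC1 and THC4. The estimated correlation of the list was 0.475, against the preset 0.01. Macrophage RNA may account for part of the difference: the median was -0.91 with macrophage level as a term (adjusted p 0.00742) and -0.79 without THC1 and THC4 (adjusted p 0.091). With sex as a term the median was -0.97 (adjusted p 0.0013) and Isg15 was at -2.33. These values rest on THC5, the only female control and the only control with a low mean macrophage marker level. Not every macrophage marker was low there, with C1qb at 1117 CPM. Macrophage RNA, sex and genotype therefore stay open.

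AT2 markers were higher in the libraries labelled Kat7-deficient, by camera at its preset correlation only (adjusted p = 0.364 with an estimated correlation, 0.0979 by fry). Library class as the whole cause is argued against by a median of 2.01 with class as a term, from 2.14 in all libraries (adjusted p 1.19e-14 by camera at the preset correlation). That fit rests on THC5 alone against K1 and K2, and on K3 alone against THC1 and THC4. The estimated correlation of the list was 0.28, against the preset 0.01. Fibroblast and macrophage markers moved apart by 4.49 log2 CPM (SE 1.75) between the groups. The controls differed among themselves: fibroblast against macrophage marker level was 5.1 against 9.06 in THC1, 8.68 against 8.87 in THC4 and 6.8 against 4.91 in THC5. With that spread, and chosen after the macrophage level was known, the contrast does not decide whether all other cells were raised alike in the controls. The contrast does not measure the epithelial share itself, so a lower share of epithelial cells in the controls is not excluded. A lower share of epithelial RNA next to particular other cells may contribute: 14 pan-epithelial genes had a median log2 fold change of 1.26, positive for 13, with Epcam at -0.45. The AT2 median was 1.84 with sex as a term (adjusted p 1.2e-07), 1.99 without THC1 and THC4 (adjusted p 1.45e-09) and 1.75 with macrophage level as a term (adjusted p 3.2e-07; a first test, replaced after its values were seen), all resting on THC5, so genotype and sex stay open.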
